A study of Mus musculus with 2 samples.

How the data were processed

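DNase-seq cuts nuclear DNA with the enzyme DNase I and sequences the cut ends, so that stretches with many cuts mark accessible chromatin. It was measured here in frontal cortex of female B6CASTF1/J mice, the first-generation hybrid of the inbred strains C57BL/6J and CAST/EiJ, at 2 months of age. Per the labels, the series holds 1 group of 2 biological replicates, each a library of its own biosample. Both biosamples are listed under the same donor record, so the labels do not say whether 2 separate animals were used, and the spread between the replicates may be partly technical.

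Each replicate came with 2 peak lists, a list of bases with a false discovery rate (FDR) and a list of footprints. Per the deposited notes, all were derived from the filtered alignment of that library alone to the mouse assembly mm10, so no list pooled the replicates. The names and versions of the aligner, the peak caller and the footprint caller are not given in the sources used here. The signal of a peak, as the authors deposited it, is a tag density that is never negative. Within each library every signal value was a whole multiple of 1 step, at a tolerance of 0.01 of a step, which is what a tag count divided by a constant of the library gives. The step was 0.00637 in replicate 1 and 0.00895 in replicate 2, a relative depth of 1.41, and the scaling constant is not stated in the sources used here. The deposited FDR file gives a q-value for runs of bases and lists only bases at or below 0.05. The deposited footprint list carries an FDR of 0.01 in every row, so it gives no ranking of footprints.

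The thresholds of the peak lists were checked against the FDR file of the same replicate. Every peak of the smaller list held a base at an FDR of 0.001 or below, against 65.0% of the peaks of the larger list in both replicates. The smaller list was used throughout and the larger one served as an alternative. The summit column held the same value in every row, so the midpoint of each peak was used as its centre. Coordinates are those of the deposited files, with starts counted from 1. The reference was GRCm38, the same build as mm10, with GENCODE M21 basic gene models, and chromosome lengths matched.

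Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures drawn in matplotlib 3.10.9. A promoter peak is one that overlaps a window of 500 bases each side of an annotated transcription start. A distal peak lies over 1000 bases from every annotated start. Peaks outside promoter windows were classed as exon, intron or intergenic by their midpoint. A gene's promoter signal is the highest signal of a peak in any of its start windows, so for a gene with several starts the peak may lie at an alternative start, and in a window that a neighbouring gene shares it cannot be assigned to either gene. Distal peaks of a gene were counted in its body and 20 kb each side, per 100 kb searched.

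Peaks of the replicates were called shared when they overlapped by at least 1 base, and chance overlap came from 100 circular shifts of the list along each chromosome (20 shifts for footprints). Overlapping peaks of both replicates were joined into shared regions, each with the highest signal of either replicate, and log2 ratios of replicate 1 over replicate 2 were centred on the median of all shared regions. Footprints were called shared when at least 50% of each overlapped.

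Gene lists and motif consensus sequences were fixed before the data were examined. The 20 lists cover cell types of the cortex, cells and brain regions that a dissection could include, tissues absent from cortex, broadly expressed genes, activity-regulated, circadian and imprinted genes, 10 X-linked genes that serve X inactivation, escape it or are common reference genes, and 8 Y-linked genes. Rorb is on both the excitatory and the circadian list, and Hprt and Pgk1 are on both the housekeeping and the X list. With 1 group there was no test between groups and no p-value was computed. Each list's value was instead placed as a percentile among 10000 random lists of protein-coding genes of the same size, matched on the decile of promoter CpG content for promoters, of searched length for distal peaks, and of the number of shared regions for the difference between replicates. The percentiles describe these libraries and are not corrected for the number of lists.

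Genes were named by a rule fixed before the data were examined: per list, the 3 members with the highest mean promoter signal among those with a promoter peak in both replicates, the first 2 in alphabetical order with none in either, and every member of the X and Y lists. The rule also named the 5 distal shared peaks with the highest mean signal, the 3 list genes with the most distal peaks in both replicates, the 3 motifs with the highest and the 3 with the lowest ratio, and every motif of a tissue control. Some genes that the rule names are not printed. Genes or motifs named outside it are said to have been chosen after their values were seen.

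Each of 24 motif consensus sequences was searched on both strands in footprints with 5 bases added each side, and in windows of the same width centred 60 bases to the side that touched no footprint. In peaks it was searched in 150 bases around the midpoint. Shares of a single library carry exact (Clopper-Pearson) binomial intervals and ratios carry conditional exact binomial intervals, both at 95%. They cover counting error only and not the spread between animals. Sequence matches of peaks on Y to other chromosomes were found with blastn 2.17.0, at an identity of at least 95% over at least 80% of the peak.

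Depth per library was read from the tag counts behind the peaks. The median peak of the smaller list was 138 tags high in replicate 1, with an exact Poisson interval of 116 to 163, and 100 tags high in replicate 2, with an interval of 81.4 to 122. These intervals are the counting error of a single peak of that height, and not the error of the median. The 5th to 95th percentiles of peak height were 47 to 779 tags in replicate 1 and 38 to 406 in replicate 2.

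The list procedures were first tested on simulated data. Of simulated lists of 20 genes whose promoter share was raised from 55% to 90% among 21859 genes, 99% were recovered. Of lists of 20 genes moved by 0.5 on the log2 scale among 17934 genes, 100% were recovered. The simulated promoter share did not depend on CpG content, whereas in replicate 1 it ran from 3.87% to 95.7% over the CpG deciles. The simulated log2 ratios were shuffled across regions, so neighbouring and CTCF regions no longer went together. These tests check the procedures and do not give their power in the real data. Alternatives tried were the larger deposited list, the upper 50% of peaks by signal, equal numbers of top-ranked peaks, a promoter window of 1000 bases, a flank of 50 kb, an overlap of 50% of both peaks, ranks in place of log2 signal, footprints without added bases, each consensus written backwards as background, and each replicate alone. Others were added after seeing the data: footprint overlap by 1 base, lists without regions that hold the CTCF consensus, and the promoter difference less that of CpG-matched random lists. The notes in text form were not analysed, since they hold no measurements.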

Results

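Accessible chromatin was mapped by DNase-seq in frontal cortex of female B6CASTF1/J mice at 2 months of age, in 1 group of 2 biological replicates. The series sets no condition against another. The comparisons its design allows are therefore between the replicates, between parts of the genome, and between gene groups of cortical cells and of other tissues. Replicate 1 was the deeper library by a factor of 1.41, judged from the steps of its signal values, with a median peak height of 138 tags against 100 tags in replicate 2. All values carry n = 2, and intervals of a single library cover counting error only.

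The first question was how many accessible regions the replicates shared. Replicate 1 held 125178 peaks over 24.9 Mb and replicate 2 held 91334 peaks over 19 Mb. Of the replicate 2 peaks, 81.6% (74498) overlapped a replicate 1 peak, against a mean of 1.97% and a maximum of 2.09% in 100 shifted copies. Of the replicate 1 peaks, 59.9% (74928) overlapped a replicate 2 peak. Promoter peaks of replicate 2 were shared in 93.9% of cases, exonic peaks in 82.6%, intronic peaks in 79.6% and intergenic peaks in 79.1%. Shared peaks were taller: their median signal was 1.10 against 0.656 for unshared peaks in replicate 1, and 1.02 against 0.537 in replicate 2. With equal numbers of top-ranked peaks, 66.7% of replicate 2 peaks, down from 81.6%, and 66.9% of replicate 1 peaks were shared. Near-equal shares follow there from the equal lengths of the lists. They do not tell why replicate 1 held more unshared peaks in the full lists.

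Signal across the 73560 shared regions correlated between the replicates with a Pearson r of 0.711 on the log2 scale and a Spearman rho of 0.680, across regions, which are not independent replicates. In the upper 50% of regions by mean signal r was 0.405. Promoter regions (12568) gave an r of 0.866 and distal regions (59300) an r of 0.601. The median log2 ratio of replicate 1 over replicate 2 was -0.01 over all shared regions, 0.76 at promoter regions and -0.15 at distal regions. The centred ratios were skewed, with a 5th percentile of -0.99 and a 95th percentile of 2.03. Distal regions with the consensus of CTCF, a zinc-finger protein of chromatin loop anchors and insulators, stood apart. Their median centred log2 ratio was 2.04 (2328 regions), against -0.17 for distal regions without it. This split by CTCF was chosen after the skew had been seen.

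**Figure D1:**
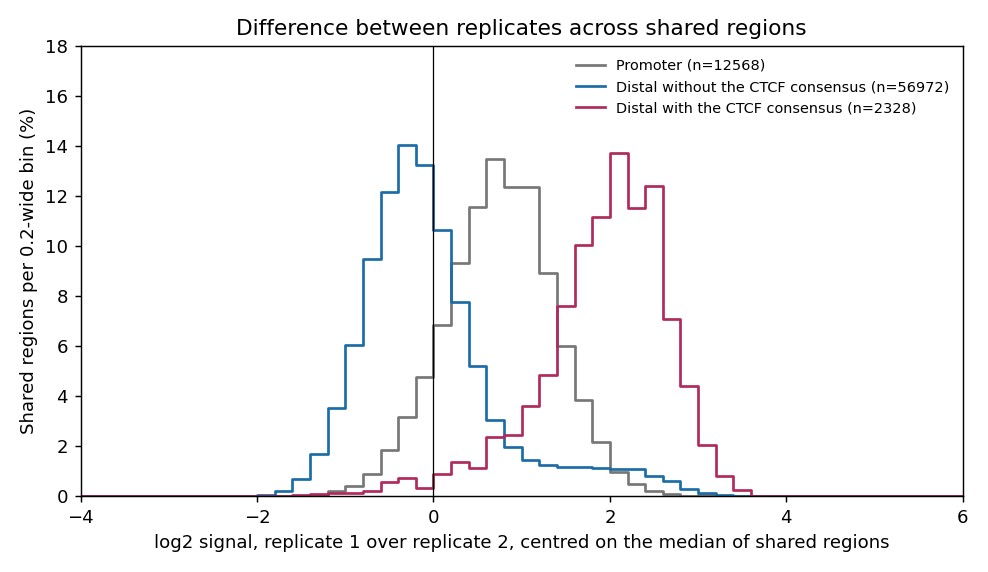
Histogram of the centred log2 signal ratio of replicate 1 over replicate 2 (x axis) in percent of the regions of each kind (y axis), for 12568 promoter regions and for distal regions with and without the CTCF consensus. The 2328 distal regions with the consensus centre near 2.04, apart from the rest of the distal regions at -0.17, which have a low shoulder on the right.

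The next comparison placed the peaks on the gene annotation. Promoter windows held 15.4% ± 0.84 of peaks (SD, n = 2), 16% (95% exact interval 15.8 to 16.2) in replicate 1 and 14.8% (14.6 to 15.0) in replicate 2. They make up 1.07% of the genome, and the share of peaks that touched them was 14.4 times that. Shifted replicate 1 peaks touched them in 1.34% of cases. Peaks were counted by any overlap, so the 1.34% is the nearer chance level and the 14.4 overstates the enrichment. Introns held 37.4% ± 0.21 of peaks, near their 34.7% of the genome. Intergenic sequence held 44.1% ± 1.27, below its 61.8%. Exons outside promoter windows held 3.13% ± 0.63, against 2.47% of the genome. Promoter peaks had a median signal of 1.95 and 1.69 in replicates 1 and 2, above the 0.751 and 0.752 of intergenic peaks. Of 21668 protein-coding genes outside Y, 61.2% had a promoter peak in replicate 1 and 51.1% in replicate 2.

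The 5 distal regions with the highest mean signal lay on 5 chromosomes. The first, on chromosome 17 from 39846781 to 39846920, had a signal of 66.2 in replicate 1 and 18.8 in replicate 2. It lies inside Rn18s-rs5, a pseudogene related to 18S ribosomal RNA, and outside every gene of the models used for the rest of the analysis. An intergenic site on chromosome 6 from 49236421 to 49236620, with Igf2bp3 as the nearest coding gene at 21564 bases, reached 45.6 and 8.69. On chromosome 3 the region from 5860361 to 5860530 gave 36.4 and 15.6 and overlaps no annotated gene. In Lars2, which encodes mitochondrial leucyl-tRNA synthetase, the site on chromosome 9 from 123461881 to 123462160 gave 40.0 and 9.14. The fifth, on chromosome 16 from 35981661 to 35981820 in the non-coding gene Gm15564 near Kpna1, gave 42.9 and 5.95. All 5 had more signal in replicate 1, by factors of 2.34 to 7.21. In replicate 1 each lay above the 99th percentile of peak signal, 8.47. Whether these sites hold sequence present in many copies was not tested, so their heights may not measure accessibility alone.

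Promoters of the pan-neuronal and excitatory lists were mostly accessible. All 20 pan-neuronal genes had a promoter peak in replicate 1 and 15 in replicate 2, at percentiles 99.9 and 86.3 among CpG-matched random lists. Syt1, the calcium sensor of synaptic vesicle release (chromosome 10, 108497650 to 109010982), had a promoter signal of 5.16 ± 0.29 (SD, n = 2). Uchl1, a neuronal ubiquitin hydrolase, had 5.03 ± 1.17. On the excitatory list, 24 of 25 genes had a promoter peak in replicate 1 and 19 in replicate 2 (percentiles 99.6 and 83.4, or 99.98 and 32.9 in the upper 50% by signal). Tle4, a corepressor of deep-layer neurons (chromosome 19, 14448150 to 14598051), reached 12.9 ± 1.95. Lmo4 had 4.31 ± 1.44, and Camk2a, the kinase of excitatory synapses (chromosome 18, 60925618 to 60988152), had 3.60 ± 0.64.

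In the full smaller list, inhibitory neuron promoters differed most between the replicates among the neuronal lists. Of 22 genes, 15 had a promoter peak in replicate 1 and 5 in replicate 2, percentiles 7.75 and 0. At the larger deposited list the counts were 21 and 12, percentiles 95.6 and 1.59, so the low rank in replicate 1 holds for the smaller list and not for the larger one. Adarb2, a marker of interneurons from the caudal ganglionic eminence, had a signal of 2.27 ± 0.06. The transcription factor gene Maf had 2.12 ± 0.16 and Cck, which encodes cholecystokinin, had 1.40 ± 0.60. In the smaller list no promoter peak was found in either replicate for Gad1 (chromosome 2, 70562042 to 70602014) or Gad2, which encode the enzymes of GABA synthesis, although 4 and 3 distal peaks lay in and around Gad1 and 3 in each replicate around Gad2. In the larger list each of the 22 genes, Gad1 and Gad2 among them, had a promoter peak in at least 1 replicate. The homeobox genes Dlx1, Dlx2, Dlx5 and Dlx6, picked out after their values were seen, had promoter peaks of 0.656 to 1.54 in replicate 1 and none in replicate 2.

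Glial lists were intermediate. On the astrocyte list 12 of 17 promoters had a peak in replicate 1 and 10 in replicate 2 (percentiles 95.9 and 92.3, or 47.8 and 84.2 in the upper 50% by signal), led by Clu (6.66 ± 2.32), the glutamine synthetase gene Glul (4.34 ± 0.77) and the glial transcription factor gene Sox9 (2.56 ± 0.26). The Glul peak lies within 500 bases of a start of Teddm2 as well. Aldh1l1 and the water channel gene Aqp4 had none. On the oligodendrocyte list 11 and 8 of 18 had one (percentiles 76.5 and 48.0; 98.4 and 84.0 at the larger list, 5.37 and 1.34 in the upper 50% by signal), with Olig1 at 2.26 ± 0.78, Pdgfra, the receptor of oligodendrocyte precursors, at 1.61 ± 1.35, and the myelin gene Mbp at 1.53 ± 0.08. For Mbp the tallest peak lay at different starts in the 2 replicates. Bcas1 and Cspg4 had none.

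Microglia went the other way from the remaining cell types: 6 of 17 promoters had a peak in replicate 1 and 11 in the shallower replicate 2, percentiles 78.1 and 100. All 6 were among the 11. Aif1, the gene of the microglial marker IBA1, had a signal of 1.52 ± 0.22 and the myeloid factor gene Irf8 had 1.39 ± 0.98. Csf1r, the growth factor receptor of microglia, and Itgam had no promoter peak. Cx3cr1, C1qa, C1qb, Fcrls and Siglech, named because they made up the difference, were listed in replicate 2 only, at signals of 0.716, 0.609, 0.564, 0.501 and 0.358. At the larger deposited list the counts were 13 in replicate 1 and 12 in replicate 2, and in the upper 50% of peaks by signal they were 4 and 3. Endothelial and mural genes had 6 of 20 promoters with a peak in replicate 1 and 1 in replicate 2, percentiles 2.41 and 0. The pericyte gene Rgs5 was the 1 in both, at 0.695 ± 0.097, while Acta2 and Cdh5 had none.

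**Figure D2:**
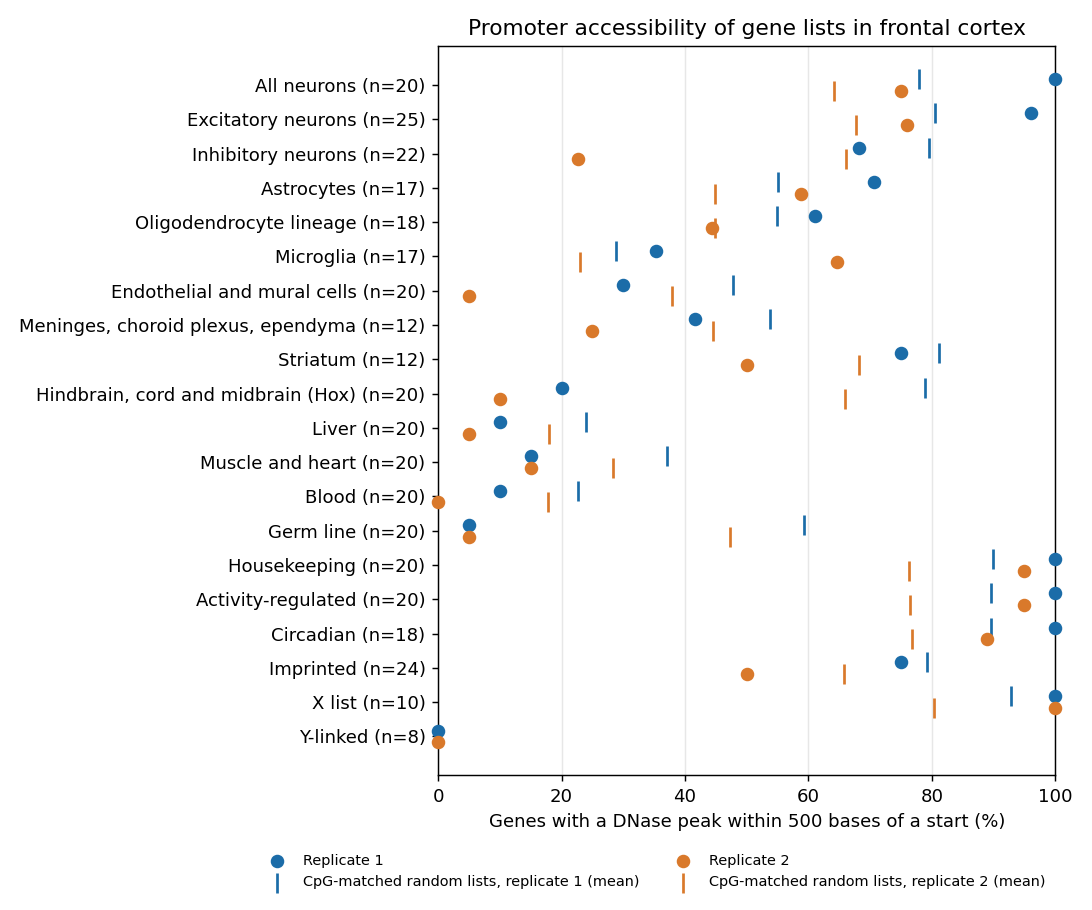
Percent of the genes of each list with a peak within 500 bases of a start (x axis) for the 20 lists (y axis), with a dot per replicate and a tick at the mean of CpG-matched random lists. Pan-neuronal, excitatory, housekeeping, activity-regulated, circadian and X lists lie at 75% or above, inhibitory neurons lie at 68.2% and 22.7%, tissues absent from cortex lie at 15% or below, and microglia is the list with the higher share in replicate 2.

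Lists of other brain regions and neighbouring cells were lower against their random lists. Of 20 genes of hindbrain, spinal cord and midbrain, most of them Hox genes, 4 and 2 had a promoter peak, where CpG-matched lists had 78.9% and 65.9%. Both percentiles were 0. The serotonin genes Tph2 (0.869 ± 0.545) and Slc6a4 (0.581 ± 0.151) were the 2 in both replicates, and En1 and Gbx2 had none. Striatal genes had 9 and 6 of 12, led by Pde10a (3.94 ± 0.18) and Rgs9 (3.48 ± 2.51), without Drd2 and Six3. Percentiles of the striatal list were 25.8 and 8.21, and 73.4 and 19.3 at the larger list (11 and 8 genes). On the list of meninges, choroid plexus and ependyma 5 and 3 of 12 had a peak (percentiles 10.9 and 4.46), and with a window of 1000 bases 6 in each replicate had one (26.8 and 59.5). Foxj1, the regulator of motile cilia, had 4.88 ± 3.21, Foxc1 had 0.768 ± 0.364 and Dcn had 0.287 ± 0.026, while Col1a1 and Folr1 had none.

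Tissues absent from cortex set the lower end. Over the liver, muscle and heart, blood and germ line lists, 8 of 80 genes (10%) had a promoter peak in replicate 1 and 5 (6.25%) in replicate 2. Over the 7 cortical cell type lists the numbers were 94 of 139 (67.6%) and 69 (49.6%). The difference was 57.6 percentage points in replicate 1 and 43.4 in replicate 2, or 50.5 ± 10.1. CpG-matched random lists gave 62.5% and 51.4% for the cortical lists and 35.8% and 27.8% for the absent tissues, a difference of 26.8 and 23.6 points from CpG content alone. Less that baseline, chosen after the values were seen, the difference was 30.8 and 19.8 points (25.3 ± 7.82), and in the upper 50% by signal it was 20.6 and 5.65. It came mainly from absent tissues lying below their random lists. Cortical lists lay above theirs in replicate 1 (67.6% against 62.5%) and below in replicate 2 (49.6% against 51.4%). They lay below in both replicates in the upper 50% by signal, and above in both at the larger list. Higher cortical accessibility than CpG content gives was therefore not established. Liver genes had 2 and 1 of 20, with Proc at 1.13 ± 0.18 and none at the albumin gene Alb or at Ahsg. Muscle and heart genes had 3 in each replicate. The tallest, at Mylpf (chromosome 7, 127208899 to 127214298; 9.56 ± 6.08), cannot be told from a peak of Tbc1d10b, which starts within 500 bases of it. Actn2 (1.64 ± 1.13) and Tnnt2 (0.807 ± 0.125) followed, and Acta1 and Ckm had none. Blood genes had 2 and 0 of 20, without Alas2. Germ line genes had 1 of 20 in each replicate, the RNA-binding protein gene Dazl (1.24 ± 0.48), and none at Ddx4 or Dppa3.

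Broadly expressed, activity-regulated and circadian genes were accessible almost throughout. All 20 housekeeping promoters had a peak in replicate 1 and 19 in replicate 2, led by Rplp0 (12.2 ± 4.92), Vcp (10.4 ± 1.39) and Rpl13a (9.90 ± 0.66). The activity-regulated list gave 20 and 19 of 20, percentiles 95.7 and 98.5. Its tallest promoter peaks were at the immediate early genes Jun (12.1 ± 0.91, chromosome 4, 95049034 to 95052222) and Egr1 (7.08 ± 2.10), and at the synaptic scaffold gene Homer1 (7.00 ± 1.10). All 18 circadian promoters had a peak in replicate 1 and 16 in replicate 2 (percentiles 94.4 and 89.4). Per1, a repressor of the molecular clock (chromosome 11, 69095217 to 69109960), reached 14.3 ± 3.88. Nr1d1, which encodes REV-ERB alpha, had 11.9 ± 1.05, and the clock output gene Dbp had 11.5 ± 1.77. On the imprinted list 18 and 12 of 24 had a peak (percentiles 27.2 and 3.86). The non-coding RNA gene Kcnq1ot1 had 7.25 ± 1.24, Inpp5f had 6.52 ± 1.02 and Ube3a had 5.20 ± 1.66, while Dlk1 and Grb10 had none.

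Distal peaks were dense around activity-regulated genes, with a median of 9.98 per 100 kb in replicate 1 and 6.76 in replicate 2, percentile 100 among length-matched random lists in both. The medians over all protein-coding genes were 4.10 and 2.24. Pan-neuronal genes had 7.19 and 5.10 (percentiles 99.8 and 99.9), excitatory genes 7.39 and 4.13 (100 rounded from 99.97, and 97.2), oligodendrocyte genes 7.94 and 4.63 (99.9 and 99.5), microglia 5.92 and 5.68 (93.7 and 99.99) and astrocytes 6.02 and 3.98 (93.7 and 97.2). Inhibitory genes had 5.92 and 2.18 (96.6 and 32.8, or 52.5 and 39.8 with a flank of 50 kb), and endothelial and mural genes 4.55 and 1.79 (69.5 and 13.1). Circadian genes had 6.49 and 4.17 (98.4 and 97.1). Rora had 52 and 31 distal peaks and Pde10a had 39 and 30.

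Distal density did not separate the cortex from other tissues as promoters did. Muscle and heart genes had 8.88 and 4.66 per 100 kb, percentiles 100 and 99.8, with Acta1 at 30.2 and 23.3. Blood genes had 5.15 and 2.27 (91.5 and 79.2), liver genes 4.44 and 2.04 (71.5 and 54.8) and germ line genes 3.91 and 1.94 (47.8 and 30.6). Imprinted genes had 5.74 and 3.0 (95.5 and 78.6), striatal genes 4.30 and 2.53 (55.5 and 62.9) and meningeal, choroid and ependymal genes 4.05 and 1.33 (52.4 and 17.1). The X list had 4.05 and 1.79 (38.4 and 13.7), hindbrain and midbrain genes 3.70 and 1.32 (46.8 and 18.2) and housekeeping genes 2.93 and 1.47 (23.0 and 16.4). With a flank of 50 kb housekeeping genes had 6.63 and 2.68, percentiles 99.05 and 66.4. The cortical median exceeded that of the absent tissues by 0.664 per 100 kb in replicate 1 and 1.29 in replicate 2. With a flank of 50 kb the difference in replicate 1 was -0.127, so no direction holds for that library.

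Between the replicates, the hindbrain, cord and midbrain list stood apart in signal. In its 12 genes with shared regions the median centred log2 ratio of replicate 1 over replicate 2 was 2.20, percentile 100, where matched random lists had a mean of 0.60. Random lists of all the other groups also lay above 0, with means from 0.37 to 0.62, so a value above 0 does not set a list apart. The gene values ran from 0.55 at Hoxb4 and Hoxb5 to 3.10 at Hoxc8, each from 1 or 2 regions. Neighbouring Hox genes share regions, so the 12 values are not independent. Meningeal, choroid and ependymal genes had 1.01 (percentile 90.7), oligodendrocyte genes 0.72 (90.2) and striatal genes 0.70 (80.4). The lowest were excitatory genes at 0.17 (3.74), endothelial and mural genes at 0.20 (5.09) and astrocytes at 0.21 (2.52), below their random means of 0.42, 0.55 and 0.57. Their signs turned on ranks (-2.40, -1.12 and -4.57 percentile points) and in distal regions without the CTCF consensus (-0.12, -0.20 and -0.10), a setting chosen after the values were seen. In those regions pan-neuronal (-0.14), housekeeping (-0.20) and X-list genes (-0.01) also turned. All distal regions without the consensus had a median of -0.17, so a value below 0 there does not set a list apart. No random lists were drawn for this setting. The other lists lay from 0.29 to 0.61, with percentiles from 6.14 (imprinted) to 66.4 (muscle and heart). Neurons minus glial and vascular lists gave -0.07, and 1.78 on ranks, so no direction was established.

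Genes of X were compared with autosomes in these female libraries, where an inactive X is present beside the active one. The comparison was not matched on CpG or gene content, so it does not measure an effect of the inactive X. X carried 20.1 and 14.3 peaks per Mb in replicates 1 and 2, against 50.9 and 37.1 on autosomes. The ratio was 0.394 (95% exact interval 0.381 to 0.408) in replicate 1 and 0.385 (0.369 to 0.401) in replicate 2. The sparsest autosomes were 3 in replicate 1, at 42.5 per Mb, and 14 in replicate 2, at 32.0 per Mb. Of 948 X-linked coding genes, 45.8% and 37.7% had a promoter peak, against 61.9% and 51.7% of 20720 autosomal genes. Median promoter signal was 2.03 and 1.47 on X, against 3.86 and 2.27 on autosomes.

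All 10 genes of the X list had a promoter peak in both replicates. Kdm6a, a histone demethylase gene that escapes X inactivation (X, 18162575 to 18279936), had the highest signal at 14.6 ± 1.57. Kdm5c, another escape gene, had 8.19 ± 0.51 and the non-coding gene Ftx of the X-inactivation centre had 7.99 ± 0.71. Ddx3x had 3.87 ± 2.20, Eif2s3x 3.36 ± 2.18, Pgk1 3.26 ± 0.53 and Hprt 1.60 ± 1.05. Jpx had 1.44 ± 0.68, and Xist, the RNA that coats the inactive X (X, 103460366 to 103483254), had 1.04 ± 0.54. None of the 8 Y-linked genes (Ddx3y, Uty, Eif2s3y, Kdm5d, Sry, Zfy1, Zfy2 and Usp9y) had a promoter peak or a distal peak in either replicate.

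Footprints are short stretches protected from DNase I inside accessible regions, as a bound protein would leave them. Replicate 1 held 445711 and replicate 2 held 280194, with median widths of 10 and 9 bases. Peaks of the smaller list contained 73.3% and 74.4% of them, and promoter windows 19.4% and 19.5%. At least 1 footprint lay in 87.5% of replicate 1 peaks and 82.7% of replicate 2 peaks. Of replicate 2 footprints, 29.8% overlapped a replicate 1 footprint by 50% of both, against 0.127% in shifted copies, and 35.7% of those inside shared peaks did. The shifts moved footprints out of peaks, so this chance level does not separate shared footprint positions from shared peaks. No shift within peaks was run.

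The footprints carried known binding sequences. CTCF had the highest mean ratio over neighbouring windows, 81.8, from 144 (95% exact interval 110 to 192) in replicate 1 and 19.4 (16.1 to 23.6) in replicate 2. In replicate 2 alone RFX (28.0) and NRF1 (27.9, interval 22.5 to 35) lay above CTCF, with NRF1 named after its value was seen. Without added bases the order turned: CTCF had 307 and NRF1 96.4 in replicate 2. The CTCF consensus lay in 1.42% of replicate 1 footprints and 0.597% of replicate 2 footprints. NFI was next by the mean of 37.6, at 62.6 (16.9 to 524) and 12.5 (3.85 to 64.5), from 102 and 27 footprints only, and in replicate 2 it lay below RFX, NRF1, CTCF, CRE and EGR. RFX had 38.1 (18.2 to 95.8) and 28.0 (13.9 to 66.0). The lowest were GATA, a family of blood and endothelial regulators, at 0.347 (0.261 to 0.455) and 0.402 (0.282 to 0.563), then by mean SOX at 0.898 and 0.687 and ROR at 0.773 and 0.855. The liver control HNF4 had 1.27 (0.887 to 1.81) and 0.974 (0.614 to 1.53), both intervals including 1. HNF1 and P53, the remaining controls, were in 0 footprints of either replicate. The windows beside footprints held 1 and 0 HNF1 sites and 0 P53 sites, so these 2 controls are not informative. In both replicates 14 of 24 motifs had an interval above 1. With each consensus written backwards as background, SOX and ROR were above 1, at 2.16 ± 0.19 and 1.97 ± 0.19.

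**Figure D3:**
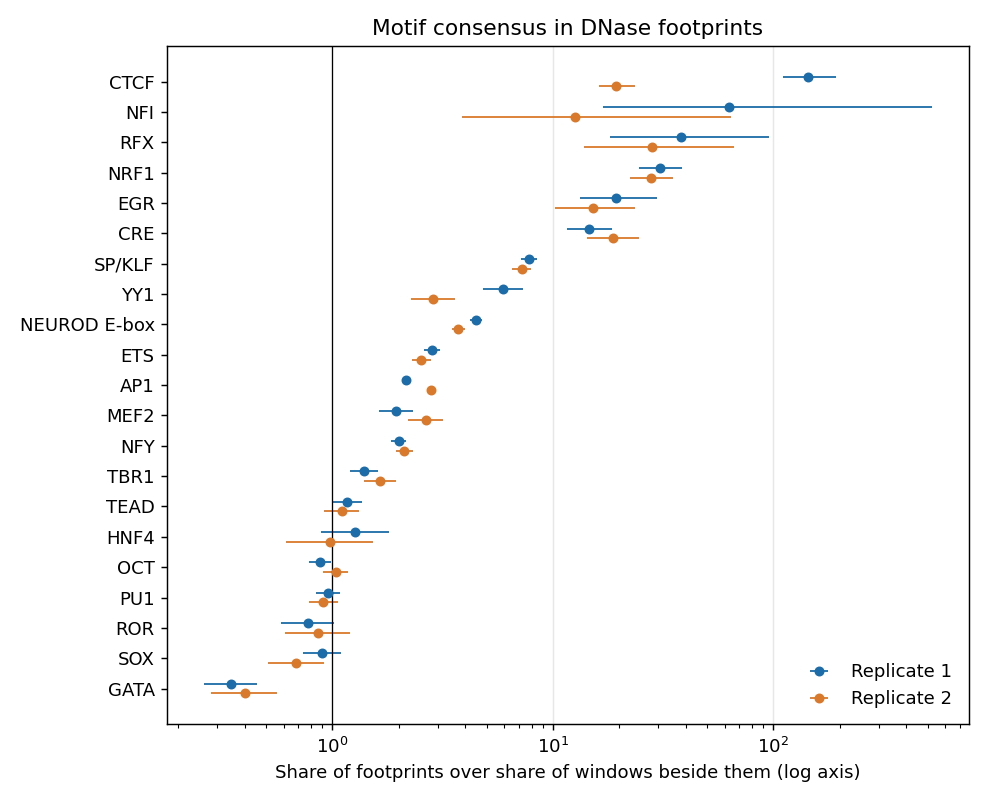
Ratio of the share of footprints with a motif consensus to the share of windows beside them (x axis, log scale), for 21 motifs with hits in both replicates (y axis; REST, HNF1 and P53 are left out for want of hits), with 95% exact intervals. CTCF lies highest in replicate 1, at 144, and below RFX and NRF1 in replicate 2, at 19.4 (307 without added bases), and GATA lies lowest in both, at 0.347 and 0.402.

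Promoter and distal peaks held different sequences. CTCF was in 6.02% of distal peaks and 0.894% of promoter peaks of replicate 1, a ratio of 6.74 (5.81 to 7.86), and in 2.79% and 0.599% in replicate 2, a ratio of 4.66 (3.73 to 5.89). The E-box of the NEUROD and NEUROG family, proneural factors, had 5.07 (4.5 to 5.73) and 5.59 (4.82 to 6.52). AP1, the site of FOS and JUN dimers, had 4.62 (4.21 to 5.09) and 5.53 (4.98 to 6.16), and its share of distal peaks was 10.6% in replicate 1 and 14.7% in replicate 2. The GC-rich sites of widely used promoter factors were at the other end. NRF1 had 0.044 (0.039 to 0.050) and 0.030 (0.025 to 0.036), SP and KLF factors 0.065 and 0.044, and ETS factors 0.107 and 0.078. Among the controls, GATA was more frequent in distal peaks in both replicates (2.17 and 2.62), HNF4 gave 1.86 and 0.999, HNF1 was in 1 distal peak of replicate 1 alone and P53 was in none. In both replicates 10 motifs had an interval above 1 and 7 an interval below 1. The ratios were not matched on base composition, so they do not separate the factors from the GC content of promoter and distal peaks.

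**Figure D4:**
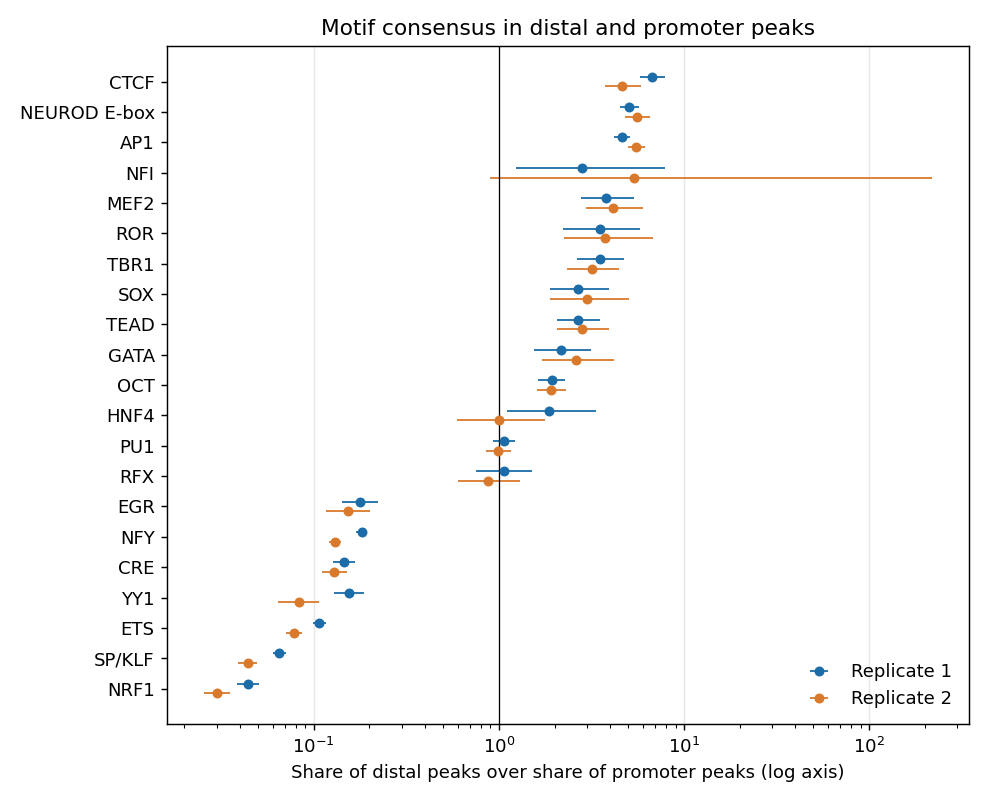
Ratio of the share of distal peaks with a motif consensus to the share of promoter peaks (x axis, log scale), for 21 motifs (y axis), with 95% exact intervals. Ratios run from 0.030 (NRF1, replicate 2) to 6.74 (CTCF, replicate 1), with 10 motifs above 1 and 7 below 1 in both replicates by their intervals and RFX, PU1 and HNF4 among those on neither side.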

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

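The test on Y-linked promoters and the look at positions along Y were chosen only after the result was seen.

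Peaks on chromosome Y were listed although both libraries are labelled female: 19 in replicate 1 and 15 in replicate 2, a signal outside the comparisons of the gene lists. A male sample or a swapped label would bring peaks at the promoters of the Y-linked genes, and 0 of 8 had one, with no peak in the first 3 Mb of Y, where these genes lie. Sequence shared with other chromosomes was the other explanation tried, and 55.9% of the 34 peaks matched another chromosome. The remaining 15 peaks all lay in a block of 22 peaks from 90718781 to 90744780, near the end of the 91.7 Mb chromosome, with signals of up to 1.95. Misplaced reads may account for the matching peaks, while for the unmatched ones this cannot be told apart from sequence of the hybrid or of X that the reference lacks. No biological explanation was tested, since the design holds no second group.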

How the results depend on the processing

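The settings of footprint overlap by 1 base, of lists without CTCF regions and of CpG-matched lists as a baseline were chosen after seeing the data. The larger deposited list raised the mean number of peaks from 108256 to 175162, and the upper 50% by signal lowered it to 54128 by construction. The share of replicate 2 peaks also found in replicate 1, and the reverse, was 66.2% and 48.3% at 50% overlap, 82.2% and 61.6% at the larger list, 78.0% and 57.3% in the upper 50%, and 66.7% and 66.9% at equal numbers. The correlation of signal was 0.680 on ranks and 0.405 in the upper 50% of regions, where the range of signal is narrower. The replicates also differed more there, with an SD of the log2 ratio of 0.984 against 0.892 over all shared regions. The promoter share of peaks was 12% at the larger list, 22.9% in the upper 50% and 18.5% with a window of 1000 bases. Intronic shares were 39.5%, 37.0% and 35.6% under the same settings, and the intergenic share was 37.0% in the upper 50%. The promoter difference between cortical and absent-tissue lists stayed positive in each replicate under every setting, from 28.1 to 63.5 percentage points, with a mean of 37.8 in the upper 50%. These values are not matched on CpG content: less the CpG-matched random lists the mean was 25.3, and single replicates ran from 5.65 to 37.5 over the settings. A positive value there does not mean that cortical lists lay above their random lists, since the absent tissues lay below theirs. The distal difference was 0.374 per 100 kb with a flank of 50 kb, 2.25 at the larger list and 1.56 in the upper 50%. Footprint sharing was 48.4% at an overlap of 1 base. Neurons minus glial and vascular lists gave -0.07 (-0.0722) without CTCF regions and reversed to 1.78 on ranks, where excitatory (-2.40), astrocyte (-4.57) and endothelial genes (-1.12) also reversed. With the consensus written backwards, SOX (2.16), OCT (34.8), ROR (1.97) and PU1 (1.96) reversed in footprints. The size and order of the footprint ratios depended on both choices. Without added bases the mean rose from 81.8 to 720 for CTCF, from 17.3 to 113 for EGR, from 29.2 to 98.5 for NRF1 and from 7.50 to 20.6 for SP and KLF factors. With the consensus written backwards NRF1 fell to 6.55, and NEUROD rose from 4.10 to 44.2 and YY1 from 4.39 to 32.3. From replicate to replicate the footprint ratio of OCT ran from 0.877 to 1.03 and that of HNF4 from 0.974 to 1.27, and the distal ratio of RFX from 0.873 to 1.06, of PU1 from 0.992 to 1.06 and of HNF4 from 0.999 to 1.86. RFX also reversed with a window of 1000 bases (1.05) and in the upper 50% (1.02). The cause of these changes was not tested except where stated. Apart from single replicates, 104 other values of single lists and motifs, each under 1 setting, moved by less than the spread between replicates. Another 105 moved by more or had no such spread to be set against. The 9 that changed direction, given above, were counted apart from both groups. Shares and densities of lists cannot change direction, since they are never negative, so the direction of these values is no check on them. The list differences between replicates on ranks are among those without a spread, and they are in another unit. A stricter set of footprints could not be run, because the footprint list holds no score. No paired analysis was possible because the series has 1 group. The depth limits what is listed: a promoter without a peak is one without a call at 138 and 100 tags of median height, not one shown to be closed.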

Other observations

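The microglia tests of counts at the larger list, of heights and of CpG content, the comparison of the sides of CTCF regions and the search of CTCF sites with 1 mismatch were chosen only after the results were seen.

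Gene families, examined after the fact, spanned nearly the whole range of promoter accessibility. Some members, Hox genes and Rpl13a among them, are also on the lists, so their values are not independent of the list results. Of 79 ribosomal protein genes, 76 (96.2%) had a promoter peak in each replicate, and of 37 NADH dehydrogenase subunit genes 35 and 34 had one. Olfactory receptor genes had one in 33 (2.91%) and 31 (2.73%) of 1134, vomeronasal receptor genes in 5 and 4 of 329, and keratin and keratin-associated genes in 8 and 9 of 110. Of 94 potassium channel genes, 69 and 44 had a promoter peak, of 19 GABA-A receptor subunit genes 13 and 8, and of 19 ionotropic glutamate receptor genes 13 and 11. Hox genes combined a median promoter CpG ratio of 0.721 with a peak at 1 and 0 of 39 promoters. The clustered protocadherins, adhesion proteins that give neurons distinct surface identities, went with the replicate: 33 of 57 had a promoter peak in replicate 1 and 7 in replicate 2. CTCF sites with up to 1 mismatch were in 3 of the 35 replicate 1 peaks in those promoters (8.57%, against 6.56% of all promoter peaks). In replicate 2 they were in 0 of 8 peaks, against 5.95% of all promoter peaks. The consensus misses sites, so these counts do not decide whether CTCF sites bear on the difference.

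Promoter accessibility followed CpG content closely. In the lowest decile of CpG content, with a median observed over expected ratio of 0.095, 3.87% of genes had a promoter peak in replicate 1 and 3.55% in replicate 2. In the highest decile, at 0.959, the shares were 95.7% and 83.2%. In the fourth decile they were 46.4% and 33.0%.

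A set of distal regions was several-fold taller in replicate 1: of 59300 distal shared regions, 13.3% were over 1 higher on the log2 scale in replicate 1 and 5.99% in replicate 2. GC content is argued against at CTCF sites, since regions with the CTCF consensus lay 2.16 above regions of the same GC content without it. In distal regions without the consensus GC content stays open. Their median rose from -0.45 in the lowest GC decile to 0.29 in the highest. The share over 1 higher in replicate 1 was 7.30% in the lowest decile and 19.3% in the highest. The SD of the log2 ratio was 4.72 times that of the tag counts, which sets single samples against counting error and decides nothing, but counting noise would act on both sides, and 89.6% of the CTCF regions were over 1 higher in replicate 1 against 0.258% in replicate 2. A candidate explanation, noticed from the CTCF shares of the peaks and tested on the same data, is that CTCF sites were recovered more strongly in replicate 1, where their median was 2.04. Whether CTCF sites are the whole of the pattern stays open: 10.2% of regions without the consensus were over 1 higher in replicate 1, but the consensus misses sites (median 1.54 in regions with 1 mismatch), and without those 5.31% were.

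No biological explanation of this difference was tested, since the series has 1 group.

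Other sequences moved less between the replicates. Among distal shared regions AP1 sites were lower in replicate 1 by a median of -0.39 (10706 regions), or -0.28 against regions of the same GC content. YY1 sites had a median of 0.89 (123 regions) and NRF1 sites 0.75 (233 regions). In the hindbrain, cord and midbrain list, the median of 2.20 became 1.47 in the 10 genes left without CTCF sites at 1 mismatch, where random lists matched to the full list had a mean of 0.60. Hoxb4, Hoxb5 and Hoxb8 (0.55 each, from a shared region) and Slc6a4 (0.59) lay below that mean.

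Microglia promoters had peaks more often in replicate 2, although it was the shallower library. Low CpG content is argued against as the whole of the difference, and as a part of it stays open. The 12 microglia promoters with a peak in both larger lists lay -0.67 (log2, replicate 1 over 2) from promoters of the same CpG deciles. That was percentile 0.08 of matched draws. The CpG-matched promoters had a median of 0.31, themselves below the 0.82 over all promoters. The height needed for a peak stays open, since its values disagree: at the larger list replicate 2 minus replicate 1 was -1 (12 against 13), as a difference in threshold would give, but the smaller list reached lower heights in replicate 1 (1st percentile 0.216 against 0.251). A further test of heights, run after this count, gave a median of -0.36, with 9 of the 12 taller in replicate 2, Cx3cr1 (0.503 and 0.716) and C1qa (0.376 and 0.609) among them, and a bootstrap interval of -0.61 to 0.31 that leaves equal heights open. A larger share of microglia or other myeloid cells in replicate 2 stays open too, since distal regions with the PU1 consensus lay -0.15 from regions of the same GC content, between the bounds set for either outcome. Over the shared regions of the 17 microglia genes the median was 0.40, with 12 genes higher in replicate 1 and 5 in replicate 2. Matched random lists had a mean of 0.58 (percentile 13.8), so these values do not decide it either.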
